A study of Mus musculus with 10 samples.

How the data were processed

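The series measured sgRNA abundance in genomic DNA of mouse iTreg cells that carried a genome-wide sgRNA library. Per the labels' protocols, naive CD4 T cells of C57BL/6 mice were transduced with the library, cultured with 2 ng/ml TGFb and 10 ng/ml IL-2, and restimulated for 3 h with 0.25 or 4 µg/ml anti-CD3. The sgRNA cassettes were amplified by PCR after DNA extraction, and MAGeCK 0.5.9.4 is the tool given, per the submitters' processing notes. The deposited table holds a raw count per sgRNA and library, per the file headers. All values in it were whole numbers, and no normalisation was recorded for them. The table names 19674 genes by symbol: 18645 symbols are in the RefSeq table of GRCm38.p6, 987 more match one of its synonyms, and 42 match neither. Symbols are given as the table has them, and current symbols are added where they differ.

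The 10 libraries were taken as 5 groups of 2 from their titles: pS6-high and pS6-low cells at each anti-CD3 dose, and input. The labels do not say whether the replicates are separate cultures or animals, nor whether equal replicate numbers share a culture. No replicate term was fitted in the tests reported. Totals ranged from 2474743 to 15558608 counts, and the median count per sgRNA from 30 to 191. Between replicates of a group, the chi-squared statistic per degree of freedom was 2.41 to 3.97, above the 1 that counting error alone gives. No molecular identifiers were used here, so counting intervals and floors cover counting error only.

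sgRNAs with at least 10 counts in at least 2 of the libraries fitted were tested: 78084 of 78633 with all libraries and 77750 with the 8 sorted libraries. Each was tested with edgeR 4.0.16 (R 4.3.3; TMM scaling, quasi-likelihood F test). The low dose, the high dose, the difference between doses, and sorted cells against input came from 1 fit of all 10 libraries with 5 groups. Both doses together came from the 8 sorted libraries with terms for dose and gate. For each gene with at least 3 sgRNAs, the ranks of its sgRNAs by signed root F were combined by robust rank aggregation (alpha 0.25, exact null distribution of uniform ranks), once towards each gate. The 2-sided p-value was adjusted by the Benjamini-Hochberg method over genes. Genes with an adjusted p below 0.05 are called, and only called genes are described as enriched in or depleted from a gate. A gene's log2 fold change is the mean over its sgRNAs, with the standard error over sgRNAs. It contains edgeR's prior count, so for genes near 0 in a gate the summed counts are given as well. CPM scales each count by the total of its library, and levels are log2(CPM + 1).

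The 25 gene lists were fixed before the data were examined, as were the tests, the thresholds and the rule for naming genes. Each list was tested with camera (limma 3.58.1) on sgRNAs, with a preset correlation of 0.01 and, as an alternative, an estimated correlation, and adjusted over the 25 lists. The lists cover mTORC1 and S6 kinase; Rag GTPases, Ragulator and FLCN; GATOR2; GATOR1 and KICSTOR; amino acid sensors; the TSC complex and other mTORC1 inhibitors; PI3K, AKT and mTORC2; positive and negative regulators of T-cell receptor (TCR) signalling; RAS, ERK and RSK; IL-2, JAK and STAT; TGF-beta and Treg identity; the COPII coat; SAGA; SWI/SNF; V-ATPase; amino acid transporters; glycolysis; cytosolic ribosomal proteins; mitochondrial ribosomal proteins; the proteasome; complex I; eIF2B, eIF4F and the integrated stress response. Genes of other lineages and olfactory receptors served as control lists. Some intended members were not found in the table used under the symbols searched and were not analysed here: Lamtor5, Bmt2, Lat, Plcg1, Csk, Taf9, Atp6v0a2, Eno1, Eif4g1, Eif2ak1, Ly6g and Hbb-b1. Genes named in the text were the 10 with the smallest p towards each gate at the low dose, at the high dose and over both doses, 5 per direction for the difference between doses and for sorted cells against input, and up to 4 members of each list, plus a fixed set of genes that included Rps6, Mtor, Rptor, Rheb, Tsc1, Tsc2, Nprl2, Nprl3, Depdc5, Mios, Wdr24, Sec31a, Ccdc101, Smarcb1, Foxp3, Cd3e and Zap70. List members beyond these are marked where they were picked after their values were seen. The fixed set held known controls of S6 phosphorylation or TCR signalling and genes of interest to the study. Sec31a, Ccdc101 and Smarcb1 of that set are also on the COPII, SAGA and SWI/SNF lists. Those lists may therefore not be independent of the study's own findings.

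Alternatives were DESeq2 1.42.0 size factors in edgeR, DESeq2's Wald test per sgRNA, no filter, at least 50 counts in 2 libraries, alpha 0.1, at least 2 sgRNAs per gene, and counts summed over the sgRNAs of a gene. Others were leaving out each gene's strongest sgRNA, a term for the replicate number, the 4 compared libraries alone, all 10 libraries for both doses together, 10000 random gene lists, and leaving out each library in turn. In that last setting the lone library of a group is assumed to vary like the other groups. Thinning every library to 2474743 counts (equal depth) was added after the data were seen. No non-targeting sgRNAs are in the table used, so scaling and a null distribution from them were not run.

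The procedure was tested on simulated data drawn from a negative binomial distribution with the real means and library sizes. At log2 changes of 0.5, 1 and 2 it recovered 13.4, 86.6 and 100 percent of changed genes for the low dose and 14.9, 89.6 and 100 percent for the high dose. For both doses together it recovered 59.7, 98.5 and 100 percent, for sorted cells against input 49.3, 100 and 100 percent, and for the difference between doses 1.49, 50.7 and 98.5 percent. False calls numbered 4 of 19419 unchanged genes for the low dose, 3 of 19219 for the high dose, 3 of 19170 for both doses together, 3 of 19419 for the difference, and 0 of 19419 for sorted cells against input. The simulation used the fitted dispersions. Only genes with 4 sgRNAs were changed, and every sgRNA of a changed gene had the same change. Real sgRNAs of a gene differ in effect, so recovery of real changes can be lower.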

Results

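The screen asked which gene knockouts change phosphorylation of ribosomal protein S6 (pS6), a readout of the kinase complex mTORC1, in induced regulatory T (iTreg) cells after stimulation of the TCR. It counted 78633 sgRNAs against 19674 genes, with 4 sgRNAs for 19642 of them, in 10 libraries of genomic DNA. The libraries formed 5 groups of 2: cells sorted as pS6-high or pS6-low after 3 h with 0.25 µg/ml anti-CD3 (the low dose) or 4 µg/ml (the high dose), and an input. Replicates 1 and 2 had total counts of 4492311 and 9300059 for pS6-high and 3136280 and 6368568 for pS6-low cells at the low dose. The high-dose totals were 2474743 and 4657642 for pS6-high and 13297009 and 7019721 for pS6-low cells, and the input had 15558608 and 8224626. Between 202 and 729 sgRNAs had no count in a library. Across sgRNAs, replicates of a group correlated with Pearson's r from 0.707 (pS6-high, high dose) to 0.902 (input), although sgRNAs are not independent replicates. Gene p-values below measure how far the sgRNAs of a gene agree in rank among all sgRNAs. Camera's p-values compare the sgRNAs of a list with all others. Neither is a direct measure of the spread between the 2 libraries of a group, which only the tests of counts summed per gene give. None of them covers cultures or animals beyond these samples. A positive log2 fold change stands for enrichment of the knockout in pS6-high over pS6-low cells.

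At the low dose, knockout of Tsc2 and Tsc1, which form the complex that inhibits mTORC1, was enriched in pS6-high cells with the smallest p-values. The log2 fold changes were 2.63 ± 0.24 and 2.29 ± 0.30 (mean ± SE over 4 sgRNAs, 2 libraries per gate). Cd5, an inhibitory receptor on T cells, was enriched by 1.53 ± 0.13, and Atp2a2, a calcium pump of the endoplasmic reticulum, by 1.37 ± 0.17. Ypel5 and Ube2h, which belong to a ubiquitin ligase system called CTLH, were enriched by 1.94 ± 0.31 and 1.69 ± 0.19. The chaperone genes Uri1 (1.97 ± 0.19) and Wdr92 (1.81 ± 0.17), the deubiquitinase gene Otub1 (1.24 ± 0.07) and Uba3 (1.16 ± 0.12), which activates NEDD8, completed the 10 genes with the smallest p in this direction.

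In the opposite direction at the low dose, knockouts of proximal TCR signalling accumulated in pS6-low cells. The kinase genes Lck and Zap70 had log2 fold changes of −2.47 ± 0.36 and −2.18 ± 0.09, the adaptor gene Lcp2 −2.28 ± 0.31 and the receptor gene Cd3d −2.36 ± 0.34. Lamtor3 (−1.94 ± 0.18) and Lamtor4 (−1.49 ± 0.09), subunits of the Ragulator that anchors mTORC1 regulators at the lysosome, moved the same way. So did Apbb1ip (−1.90 ± 0.10), an adaptor gene of integrin activation, the integrin gene Itgav (−1.53 ± 0.09) and the actin-branching genes Arpc4 (−1.65 ± 0.13) and Actr2 (−1.56 ± 0.20).

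At the low dose, 106 of 19640 genes were called as enriched in pS6-high and 177 as enriched in pS6-low cells by edgeR and rank aggregation. Adjusted p was 2.14e-10 for Tsc2 and 6.31e-09 for Lck, and 1302 genes had an unadjusted p below 0.05. The median log2 fold change of called genes was 0.98 towards pS6-high and −1.15 towards pS6-low. The 106 genes became 59 without pS6-low replicate 1, 59 without pS6-high replicate 2 and 47 without pS6-low replicate 2. The 177 became 69 without pS6-high replicate 2, where the call of Actr2 was lost (adjusted p = 0.0580), and 98 without pS6-low replicate 2.

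At the high dose, Myl6, a myosin light chain gene, gave the strongest enrichment in pS6-high cells, at 3.51 ± 0.12, followed by Atp2a2 at 2.17 ± 0.03. The plasma membrane calcium pump gene Atp2b1 was enriched by 1.62 ± 0.10 and the cell-cycle inhibitor gene Cdkn1b by 1.46 ± 0.12. Tsc2 was enriched by 1.56 ± 0.11 and Tsc1 by 1.69 ± 0.23. Tceb2 (now Elob, a partner of cullin ligases) reached 2.12 ± 0.20, Dbf4 1.99 ± 0.18, Wdr82 1.93 ± 0.22, Rbbp4 1.68 ± 0.10 and Nrbp1 1.30 ± 0.10. The summed counts of the Myl6 sgRNAs were 658 and 1368 in the pS6-high libraries and 299 and 189 in the deeper pS6-low libraries, an 11.3-fold difference in mean CPM.

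Depletion from the pS6-high gate at the high dose left some knockouts close to absent there. The summed counts of the Lck sgRNAs were 9 and 22 in pS6-high and 3382 and 1484 in pS6-low libraries, a 55.7-fold difference in mean CPM. For Actr2 they were 26 and 14 against 3929 and 2050 (43.5-fold), for Rptor, which recruits mTORC1 substrates, 22 and 57 against 3315 and 1674 (23.1-fold), and for Lamtor4 33 and 77 against 4192 and 2075 (20.5-fold). Log2 fold changes were −5.69 ± 0.29 for Lck, −6.05 ± 0.47 for Actr2, −4.80 ± 0.66 for Rptor and −4.37 ± 0.23 for Lamtor4. Cd3d (−4.96 ± 0.37), Lamtor3 (−4.71 ± 0.24), Rraga (−4.36 ± 0.41), Lcp2 (−4.31 ± 0.46), Lamtor2 (−4.26 ± 0.63) and Actr3 (−3.51 ± 0.22) completed the 10 genes with the smallest p towards pS6-low cells.

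The high dose gave 86 genes called towards pS6-high and 287 towards pS6-low among 19640 tested by edgeR and rank aggregation, with adjusted p of 1.08e-12 for Myl6 and 3.30e-10 for Lamtor4. Unadjusted p was below 0.05 for 1390 genes, and the median log2 fold change of genes called towards pS6-low was −1.68. Without pS6-high replicate 2 the counts were 56 and 164, and without pS6-high replicate 1 the 287 genes became 187.

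**Figure D1:**
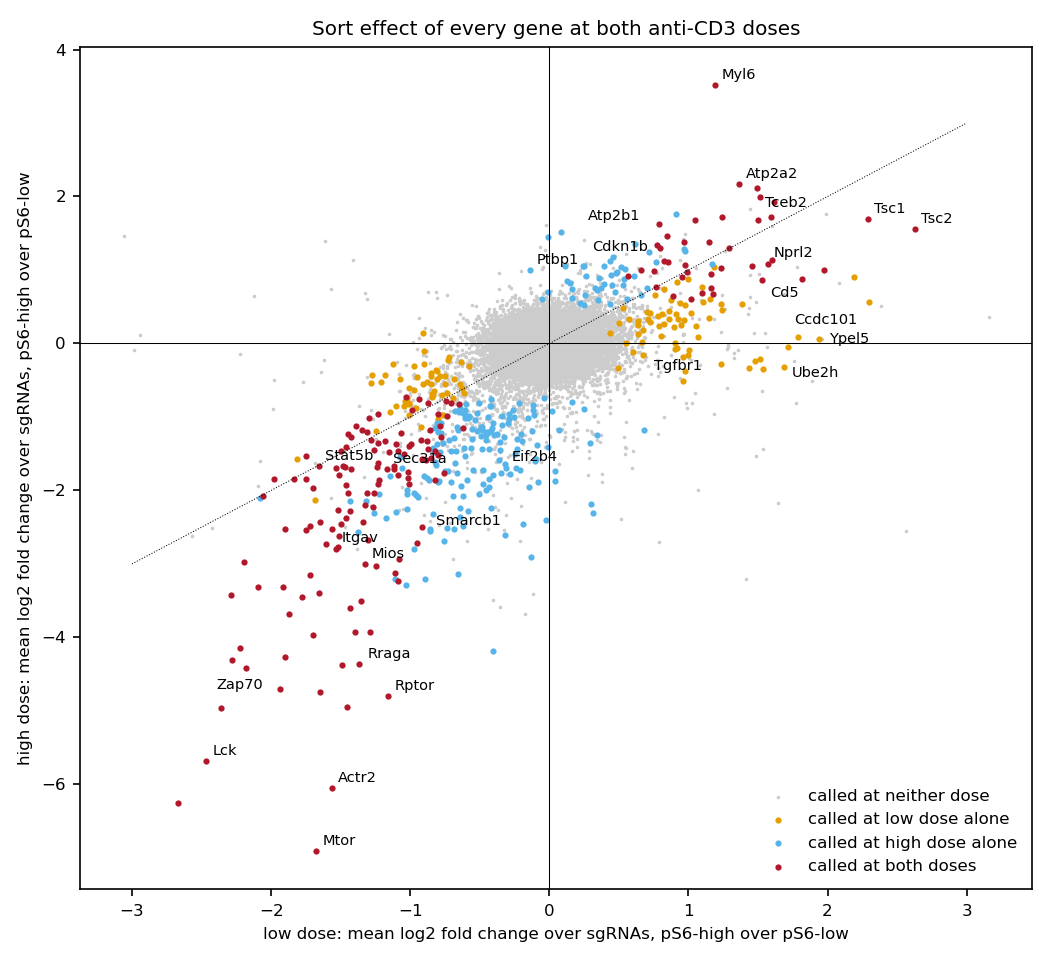
Mean log2 fold change over sgRNAs (pS6-high over pS6-low) of every gene tested, at the low dose (x axis) and the high dose (y axis), 2 libraries per gate and dose; colours give the doses at which a gene was called and the dotted line marks equal change. Tsc2 lies at 2.63 and 1.56, Myl6 at 1.19 and 3.51, and Lck at −2.47 and −5.69.

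Over both doses together, which sets 4 pS6-high against 4 pS6-low libraries, the 10 genes with the smallest p towards pS6-high were Myl6 (2.59 ± 0.05), Tsc2 (2.05 ± 0.16), Tsc1 (1.97 ± 0.18), Tceb2 (1.85 ± 0.14), Atp2a2 (1.80 ± 0.09), Dbf4 (1.79 ± 0.10), Atp2b1 (1.24 ± 0.08), Cd5 (1.19 ± 0.10), Cdkn1b (1.18 ± 0.08) and Nrbp1 (1.07 ± 0.08). Those towards pS6-low were Lck (−3.73 ± 0.24), Cd3d (−3.44 ± 0.22), Actr2 (−3.24 ± 0.25), Lcp2 (−3.20 ± 0.35), Lamtor3 (−3.10 ± 0.18), Zap70 (−3.10 ± 0.13), Arpc4 (−3.05 ± 0.11), Lamtor2 (−2.89 ± 0.19), Lamtor4 (−2.78 ± 0.14) and Itgav (−2.16 ± 0.20). With dose as a term in edgeR, 157 genes were called towards pS6-high and 363 towards pS6-low among 19555, with adjusted p of 1.75e-11 for Atp2a2 and 6.58e-10 for Lck. The smallest counts without any 1 of the 8 libraries were 121 and 276.

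The doses shared 40 genes called towards pS6-high, where 0.464 would be shared by chance, and 122 called towards pS6-low, where chance gives 2.59. No gene was called in opposite directions at the 2 doses, either by edgeR or with DESeq2's test per sgRNA, while 7 genes had an unadjusted p below 0.05 in opposite directions with edgeR.

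Within the mTORC1 machinery, knockout of Mtor, Rptor and Rheb moved cells to the pS6-low gate at both doses. Low-dose log2 fold changes were −1.67 ± 0.16 for Mtor, −1.16 ± 0.17 for Rptor and −1.11 ± 0.38 for Rheb, and Mlst8 followed at −1.23 ± 0.20. The high-dose value of Mtor, −6.90 ± 1.79, rests on summed counts of 2 and 26 in pS6-high against 2562 and 1098 in pS6-low libraries, with 1 of its sgRNAs at 0 in both pS6-high libraries. Its mean CPM differed 54.6-fold. Rheb (−3.12 ± 0.94) and the S6 kinase gene Rps6kb2 (−2.48 ± 0.12, 4 of 4 sgRNAs) were also called at the high dose, where 6 of the 11 genes on the list were called, against 4 at the low dose. Adjusted over the list alone, 6 and 7 were called. Camera gave adjusted p = 1.17e-18 at the low and 2.93e-81 at the high dose (0.00947 and 0.00152 with an estimated correlation). Rps6, which encodes S6 itself, was not called at the low (−0.28 ± 0.82) or high dose (−1.52 ± 0.38, adjusted p = 1 at both), and had fewer than 3 sgRNAs past the filter in the 8 sorted libraries. DESeq2's test ended the low-dose call of Rptor (adjusted p = 0.0560). Without pS6-high replicate 2 at the low dose the calls of Rptor (0.127) and Mlst8 (0.785) were lost there, and without pS6-low replicate 2 that of Mlst8 (0.215).

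The lysosomal arm that carries amino acid signals to mTORC1 followed the same direction. Of 12 genes on the list of Rag GTPases, Ragulator and FLCN, 5 were called towards pS6-low at each dose, namely Rraga, Lamtor1, Lamtor2, Lamtor3 and Lamtor4, with Lamtor1 at −1.70 ± 0.26 and −3.97 ± 0.50. All 5 genes of GATOR2, which activates this arm, were called towards pS6-low at the high dose: Mios, Wdr24 (−3.29 ± 0.38), Seh1l (−4.15 ± 0.36), Sec13 (−2.80 ± 0.57) and Wdr59 (−1.71 ± 0.26). The low dose had 3 of them called, Mios at −1.33 ± 0.25 and Seh1l at −2.23 ± 0.51 among them, while Wdr24 was not (−1.03 ± 0.27, adjusted p = 0.196). GATOR1, its inhibitory counterpart, moved the other way: Nprl2 (1.57 ± 0.35 and 1.09 ± 0.14), Nprl3 (1.60 ± 0.21 and 1.14 ± 0.15) and Depdc5 (1.02 ± 0.10 and 0.61 ± 0.12) were called towards pS6-high at both doses. Camera's adjusted p for the Rag, GATOR2 and GATOR1 lists lay between 2.92e-92 and 2.43e-06 at the 2 doses, and between 0.000292 and 0.00746 with an estimated correlation. Among the 5 amino acid sensor genes (Sesn3 0.49 ± 0.20 at the low dose), edgeR called 0 at either dose, as did DESeq2, with 1 and 0 at an unadjusted p below 0.05 (camera's adjusted p = 0.312 and 0.880). DESeq2's test called 1 of the 5 GATOR2 genes at the low dose, and lost Mios (adjusted p = 0.352) and Wdr59 (0.0656). Single libraries decided several of these calls. The low-dose call of Rraga was lost without pS6-high replicate 2 (adjusted p = 0.412), and those of Mios (0.161) and Wdr59 (0.666) without pS6-low replicate 2. Nprl2 was lost at the high dose without pS6-high replicate 2 (0.0777), and Depdc5 without any of pS6-high replicates 1 (0.377) and 2 (0.564) and pS6-low replicates 1 (0.266) and 2 (0.229).

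Among other inhibitors of mTORC1, Ddit4, which acts through the TSC complex, was called at the low dose (0.78 ± 0.15). The list had 3 of 10 genes called at the low and 2 at the high dose, with camera's adjusted p of 7.34e-16 and 3.49e-05 (0.00190 and 0.00925 with an estimated correlation). The call of Ddit4 was lost without pS6-high replicate 2 (adjusted p = 0.323), pS6-low replicate 1 (0.205) or pS6-low replicate 2 (0.0635). On the list of PI3K, AKT and mTORC2, Pik3cd alone was called, at the low dose (−0.88 ± 0.11, adjusted p = 0.0264). That call was lost without pS6-high replicate 2 (0.636), pS6-low replicate 1 (0.190) or pS6-low replicate 2 (0.935). At the high dose 0 of the 12 genes were called by edgeR or DESeq2, and 2 had an unadjusted p below 0.05. Camera gave this list adjusted p = 0.286 and 0.911. Its mean was −0.11 and its median 0.00 at the low dose, and at the high dose the mean was −0.02, the median 0.05 and the direction of the test towards pS6-high.

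Genes of TCR signalling were called in both directions. Of 21 positive regulators, 12 were called towards pS6-low at each dose (14 and 13 adjusted over the list alone), with a median of −1.25 at the low and −1.70 at the high dose. Cd3e changed by −1.40 ± 0.41 and −3.93 ± 1.17, Cd3g by −1.78 ± 0.47 and −3.44 ± 0.34, and Zap70 reached −4.42 ± 0.29 at the high dose. Of 19 negative regulators, 4 were called towards pS6-high at the low and 3 at the high dose. Besides Cd5, these were the phosphatase genes Ptpn6 (0.95 ± 0.20 and 0.91 ± 0.24) and Ptpn2 (0.66 ± 0.09 at the low dose) and, at the low dose, the ubiquitin ligase gene Cbl (0.94 ± 0.14). Camera's adjusted p was 1.17e-58 and 5.02e-129 for the positive and 6.19e-11 and 6.06e-05 for the negative regulators (0.00494, 0.00152, 0.00190 and 0.00746 with an estimated correlation). At the low dose Cd3e (adjusted p = 0.277) was lost without pS6-low replicate 2, which also ended the calls of Ptpn2 (0.166), Ptpn6 (0.0653) and Cbl (0.445). Without pS6-high replicate 2 at that dose Ptpn2 (0.476), Ptpn6 (0.0504) and Cbl (0.127) were lost, and without pS6-low replicate 1 Ptpn6 (0.258) and Cbl (0.0787). Cd5 (0.223) was lost at the high dose without pS6-high replicate 2, and Ptpn6 without pS6-high replicate 1 (0.270) or 2 (0.251) or pS6-low replicate 1 (0.119) or 2 (0.248).

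Of branches downstream of the receptors, the list of RAS, ERK and RSK had 2 of 15 genes called at each dose. The IL-2, JAK and STAT list had 3 of 11 called at each dose, and 4 of the 8 still tested over both doses. Shoc2 (−0.85 ± 0.31 and −1.56 ± 0.33), which acts in the RAS and ERK cascade, was called towards pS6-low at both doses. Camera gave the list of 15 genes adjusted p = 0.0138 at the low dose, adjusted p = 0.185 with an estimated correlation, and 1.11e-05 at the high dose, 0.0476 with an estimated correlation. The low-dose result of that list was lost without pS6-high replicate 2 (adjusted p = 0.346) or pS6-low replicate 2 (0.0658). The IL-2 signal transducers Stat5b (−1.66 ± 0.12 and −1.67 ± 0.40) and Stat5a (−1.23 ± 0.09 and −1.36 ± 0.13) were called towards pS6-low at both doses. Their inhibitors were called towards pS6-high, Socs1 at the low dose (0.53 ± 0.00, 3 sgRNAs) and Cish at the high dose (1.06 ± 0.18). Camera gave the IL-2, JAK and STAT list adjusted p = 0.107 and 0.520, and its mean of −0.43 at the high dose stood beside a median of 0.00. At the low dose, leaving out pS6-high replicate 2 or pS6-low replicate 2 ended the calls of Shoc2 (adjusted p = 0.188 and 0.0822), Stat5a (0.376 and 0.424) and Socs1 (0.785 and 0.159). Without pS6-high replicate 2 Stat5b was lost too (0.0580), without pS6-low replicate 1 Stat5a (0.0597) and Socs1 (0.471), and without pS6-high replicate 1 Socs1 (0.137). At the high dose, Stat5a was lost without pS6-high replicate 1 (0.173) or pS6-low replicate 1 (0.0621), and Stat5b without pS6-high replicate 1 (0.0704) or 2 (0.525).

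**Figure D2:**
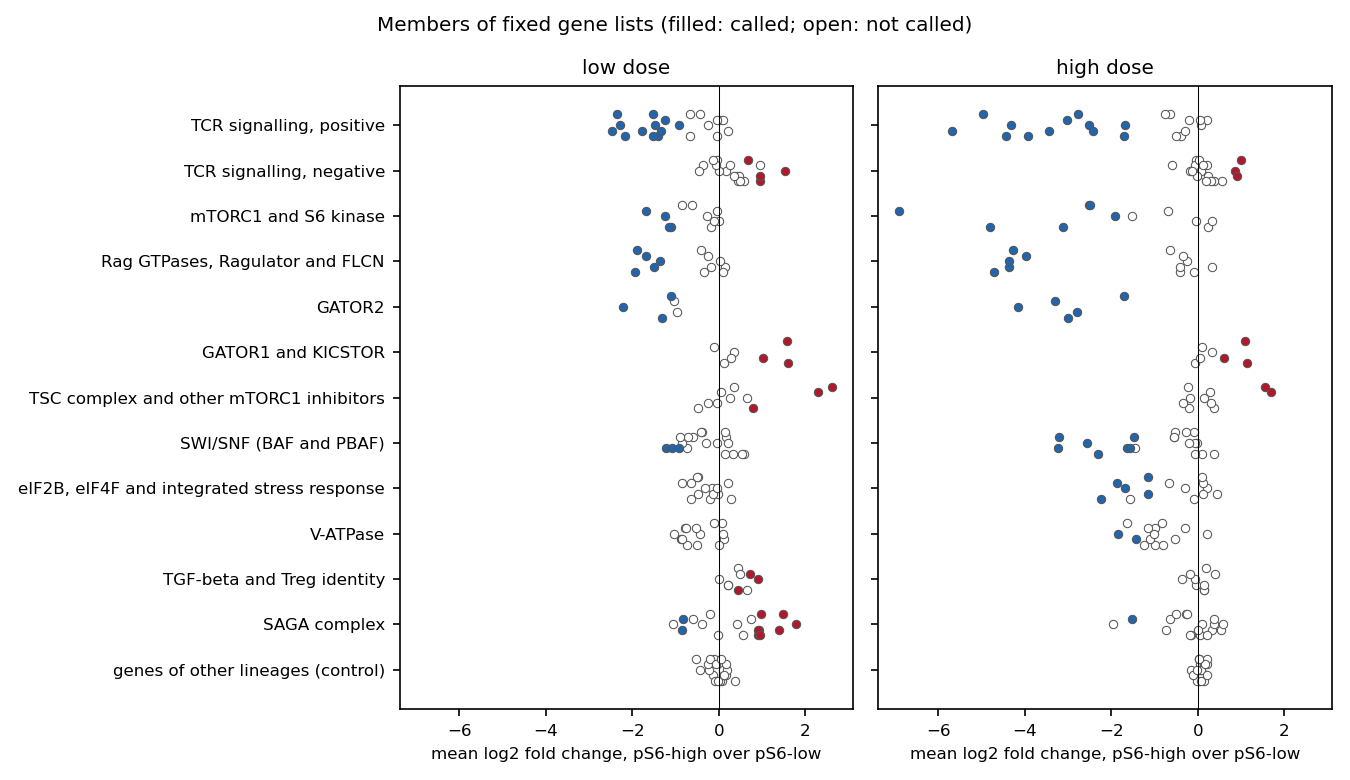
Mean log2 fold change over sgRNAs (pS6-high over pS6-low) of the members of 13 fixed lists at the low and high dose, 2 libraries per gate; each point is a gene, filled where it was called and open where it was not. Members of GATOR2 lie between −4.15 and −1.71 at the high dose, and the called members of GATOR1 between 0.61 and 1.14.

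Chromatin complexes also held called genes. Ccdc101 (now Sgf29), a histone-binding subunit of the SAGA coactivator, was enriched in pS6-high cells at the low dose by 1.79 ± 0.15 and not at the high dose (0.09 ± 0.15, adjusted p = 1). With it, Tada1 (1.48 ± 0.12), Taf5l (0.96 ± 0.23) and 5 more SAGA genes were called towards pS6-high at the low dose. Of SAGA's deubiquitinase module, Atxn7l3 (−0.85 ± 0.32) and Eny2 (−0.83 ± 0.08) were called towards pS6-low at the low dose, while the catalytic subunit gene Usp22 was not called at either dose (0.42 ± 0.12 and 0.58 ± 0.14) and went to pS6-high over both (0.50 ± 0.05, adjusted p = 0.0161). Usp22 kept that call only without pS6-high or pS6-low replicate 1 of the low dose (0.0667 to 0.279 otherwise). Only Taf12 of the 18 SAGA genes was called at the high dose, towards pS6-low (−1.53 ± 0.12), and DESeq2's test called 0 (Taf12 0.0628). Camera gave SAGA adjusted p = 9.92e-08 at the low dose (0.0149 with an estimated correlation), 0.383 at the high dose, and 0.0355 over both doses, adjusted p = 0.398 with an estimated correlation. Without pS6-high replicate 2 at the low dose the calls of Atxn7l3 (0.182) and Eny2 (0.245) were lost, the latter also without pS6-low replicate 2 (0.442) and with DESeq2's test (0.105). The result of SAGA over both doses was lost without each low-dose library: pS6-high replicates 1 (0.254) and 2 (0.127) and pS6-low replicates 1 (0.0917) and 2 (0.505). Taf12 was lost without any of the 4 high-dose libraries, pS6-high replicates 1 (0.133) and 2 (0.557) and pS6-low replicates 1 (0.107) and 2 (0.139).

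The chromatin remodeller SWI/SNF went to pS6-low, with 3 of 19 genes called at the low and 7 at the high dose. Smarcb1 was called at the high dose (−2.56 ± 0.43) and not at the low dose (−0.86 ± 0.42, adjusted p = 0.202). Smarca4 changed by −1.09 ± 0.09 and −3.23 ± 0.34, Arid1a by −1.23 ± 0.18 and −1.63 ± 0.36, and Smarcd2 by −0.91 ± 0.19 and −1.57 ± 0.31. Camera gave SWI/SNF adjusted p = 1.17e-05 at the low dose, adjusted p = 0.0586 with an estimated correlation, and 5.42e-29 at the high dose, 0.00492 with an estimated correlation. The low-dose calls of Arid1a (0.198), Smarca4 (0.386), Smarcd2 (0.483) and the SWI/SNF list itself (0.114) were lost without pS6-high replicate 2, those of Arid1a (0.0757) without pS6-low replicate 2 and of Smarca4 (0.521) without pS6-low replicate 1.

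Sec31a, an outer coat gene of the COPII vesicles that leave the endoplasmic reticulum, was called towards pS6-low at both doses (−1.17 ± 0.15 and −1.71 ± 0.31). It was the only gene called at either dose on the COPII list of 12, which leaves out Sec13, a coat gene placed with GATOR2 above. Preb (−0.98 ± 0.11) and Sec24c (−0.70 ± 0.19) were called over both doses together. Camera gave this list adjusted p = 0.00702 at the low dose, adjusted p = 0.0538 with an estimated correlation, and 0.00245 at the high dose, 0.0296 with an estimated correlation. Without pS6-high replicate 2 at the low dose the calls of Sec31a (adjusted p = 0.122) and of the list (0.239) were lost there, as they were without pS6-low replicate 2 (0.270 and 0.0722). Over both doses, Sec24c was lost without pS6-high replicate 2 (0.166) or pS6-low replicate 2 (0.0702) of the high dose or pS6-high replicate 2 of the low dose (0.0669), and Preb without pS6-high replicate 2 of the high dose (0.0520).

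Genes of the response to TGF-beta, the cytokine that induces iTreg cells, and of Treg identity were called towards pS6-high at the low dose: Tgfbr1 (0.90 ± 0.11), Smad2 (0.73 ± 0.11) and Foxp3 (0.43 ± 0.59). Camera gave the list of 9 genes adjusted p = 6.19e-11 (0.00264 with an estimated correlation). The high dose had 0 of them called by edgeR and DESeq2, 1 had an unadjusted p below 0.05, and camera gave adjusted p = 0.520. Over both doses Smad2, Smad3 (0.32 ± 0.11) and Tgfbr1 were called, with camera's adjusted p = 1.37e-05, adjusted p = 0.058 with an estimated correlation. Foxp3 rested on sgRNAs that moved apart, 2 of 4 towards each gate, and its call was lost with DESeq2's test (0.392), without pS6-high replicate 2 (0.127) and without pS6-low replicate 2 (0.0534). Tgfbr1 was lost at the low dose without pS6-high replicate 1 (0.0944) or pS6-low replicate 2 (0.227), and Smad2 without pS6-high replicate 1 (0.0534) or 2 (0.0968) or pS6-low replicate 1 (0.243) or 2 (0.0618). Over both doses Smad3 kept its call only without pS6-low replicate 1 or 2 of the high dose (0.0607 to 0.251 without each other library). Tgfbr1 lost it without each low-dose library and without pS6-high replicate 1 of the high dose (0.115 to 0.833).

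The translation factor eIF2B, the target of the integrated stress response, had all 5 subunit genes called towards pS6-low at the high dose, among them Eif2b2 (−2.24 ± 0.34), Eif2b5 (−1.86 ± 0.45), Eif2b4 (−1.69 ± 0.25) and Eif2b3 (−1.14 ± 0.16). At the low dose edgeR and DESeq2 called 0 of the 14 genes on its list, with 4 at an unadjusted p below 0.05. Camera gave adjusted p = 0.000181 at the low and 1.64e-10 at the high dose (0.0256 and 0.00711 with an estimated correlation). Without pS6-high replicate 1 of the high dose Eif2b3 (adjusted p = 0.136) and Eif2b5 (0.101) were lost, and Eif2b3 also without replicate 2 (0.204). The proton pump V-ATPase had Atp6v1a called towards pS6-low at both doses (−0.87 ± 0.18 and −1.43 ± 0.35) and Atp6v1b2 at the high dose (−1.84 ± 0.33). Adjusted over the list alone, 4 of its 14 genes were called at the low and 11 at the high dose, and camera gave 1.31e-06 and 2.30e-14 (0.0256 and 0.00746 with an estimated correlation). Atp6v1a was lost at the low dose without pS6-high replicate 2 (0.386), pS6-low replicate 1 (0.493) or pS6-low replicate 2 (0.522). Its high-dose call was lost without pS6-high replicate 2 (0.313), and Atp6v1b2 without pS6-high replicate 1 (0.293) or 2 (0.433) or pS6-low replicate 1 (0.0964).

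In 8 further lists 0 genes were called at either dose by edgeR or DESeq2. Cytosolic ribosomal protein sgRNAs had median counts of 3 and 4 in the pS6-high libraries of the high dose. Only 46 of these genes could be tested over both doses, so their lack of calls does not show a lack of effect. At an unadjusted p below 0.05 were 4 and 8 of 80 cytosolic ribosomal protein genes at the low and high dose, 4 and 4 of 75 mitochondrial ribosomal protein genes, 2 and 4 of 39 proteasome genes, 4 and 0 of 42 complex I genes, 2 and 0 of 14 glycolysis genes, and 1 and 2 of 12 amino acid transporter genes. Cytosolic ribosomal proteins had a mean of −0.18 at the low dose (camera's adjusted p = 0.0154, adjusted p = 0.206 with an estimated correlation) and −1.03 at the high dose (3.56e-05, 0.0768 with an estimated correlation). Without pS6-low replicate 2 the low-dose mean turned to 0.54 (0.177), and without pS6-high replicate 2 the list was lost at the low (0.358) and high dose (0.0536). Complex I had a mean of −0.17 at the low dose (0.000815, 0.0473 with an estimated correlation; 0.0765 without pS6-low replicate 1) and −0.03 at the high dose (0.929). The proteasome had means of −0.12 (0.625) and −0.36 (0.0110, 0.0200 with an estimated correlation; 0.106 without pS6-high replicate 1). Amino acid transporters had means of 0.00 (0.822, with a median of −0.01) and 0.04 (0.0226, 0.176 with an estimated correlation), and the high-dose mean turned to −0.09 without pS6-high replicate 2 (0.410; 0.0505 without pS6-low replicate 1). Glycolysis (0.326 and 0.559, mean 0.01 and median −0.07 at the low dose) and mitochondrial ribosomal proteins (0.536 and 0.485) did not reach the threshold. Of the control lists, genes of other lineages had 1 and 0 of 22 at an unadjusted p below 0.05 (camera's adjusted p = 0.945 and 0.252, low-dose mean −0.02 and median 0.04). Olfactory receptor genes had 32 and 21 of 1079 (0.773 and 0.982). In total camera's adjusted p was below 0.05 for 16 lists at the low dose, 15 at the high dose and 17 over both, and for 12, 13 and 12 with an estimated correlation.

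Equal depth ended further calls given above. For the low dose these were Atp6v1a (adjusted p = 0.335), Cbl (0.144), Cd3e (0.202), Pik3cd (0.267), Ptpn2 (0.0642), Rraga (0.159), Sec31a (0.139), Smarcd2 (0.169), Socs1 (0.390), Wdr59 (0.0748) and the list of RAS, ERK and RSK (0.0613). For the high dose they were Atp6v1a (0.0532), Atp6v1b2 (0.211), Depdc5 (0.325), Ptpn6 (0.129) and Taf12 (0.155), and over both doses Preb (0.0663), Smad3 (0.169) and Tgfbr1 (0.0768).

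The same sort at 2 doses allowed a test of whether a knockout's effect depends on the strength of TCR stimulation. The actin-branching gene Actr2 went further towards pS6-low at the high dose, by −4.48 ± 0.28 (difference of log2 fold changes, high minus low dose, over 4 sgRNAs). So did Rptor (−3.64 ± 0.63), Rraga (−2.99 ± 0.45), Lamtor4 (−2.88 ± 0.17) and Lamtor3 (−2.77 ± 0.22), and, among the always-named genes, Mtor (−5.23 ± 1.68), Cd3e (−2.53 ± 1.03), Wdr24 (−2.26 ± 0.16), Zap70 (−2.24 ± 0.26), Rheb (−2.01 ± 0.57) and Smarcb1 (−1.70 ± 0.26). Ccdc101 (−1.70 ± 0.12) and Tsc2 (−1.07 ± 0.14) also had negative differences, since their enrichment in pS6-high cells was larger at the low dose. Myl6 (2.32 ± 0.35), Ptbp1 (1.13 ± 0.24) and Atp2a2 (0.80 ± 0.15) went further towards pS6-high at the high dose, while Atp2b1 (0.83 ± 0.07, adjusted p = 0.0619) and Tmx2 (0.72 ± 0.35, adjusted p = 0.1) were not called.

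By edgeR's interaction contrast, 3 genes differed towards pS6-high and 55 towards pS6-low at the high dose, of 19640 tested, with adjusted p of 1.12e-09 for Actr2 and 9.67e-09 for Myl6. An unadjusted p below 0.05 was reached by 1108 genes. Of the 55, 42 were also called towards pS6-low at the high dose, 10 were called towards pS6-high at the low dose, and 3 were called at neither: Suv39h1, Dyrk1a and Eif5, named here after their values were seen. The 55 became 34 without pS6-low replicate 2 of the low dose and 32 without pS6-high replicate 2 of the high dose, and the 3 became 5 without pS6-high or pS6-low replicate 1 of the low dose. Wdr24 lost its call without pS6-high replicate 1 of the high dose (adjusted p = 0.0733) and Zap70 without pS6-high replicate 2 (0.190). Ccdc101 lost it without pS6-high replicate 1 of the low dose (0.229) or pS6-low replicate 1 of the high dose (0.0781). The call of Atp2a2 was lost without pS6-high replicate 1 (0.152) or pS6-low replicate 1 (0.0895) of the high dose and pS6-high replicate 2 (0.638) or pS6-low replicate 1 (0.692) of the low dose. That of Ptbp1 was lost without pS6-high replicate 2 (0.603) or pS6-low replicate 2 (0.275) of the high dose and pS6-high replicate 1 (0.189) or pS6-low replicate 2 (0.0575) of the low dose. Tsc2 kept its call only without pS6-high replicate 1 of the low dose or pS6-low replicate 1 of the high dose (0.0571 to 0.414 otherwise), and Smarcb1 only without pS6-high replicate 2 of the low dose or pS6-low replicate 1 of the high dose (0.0610 to 0.868 otherwise).

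**Figure D3:**
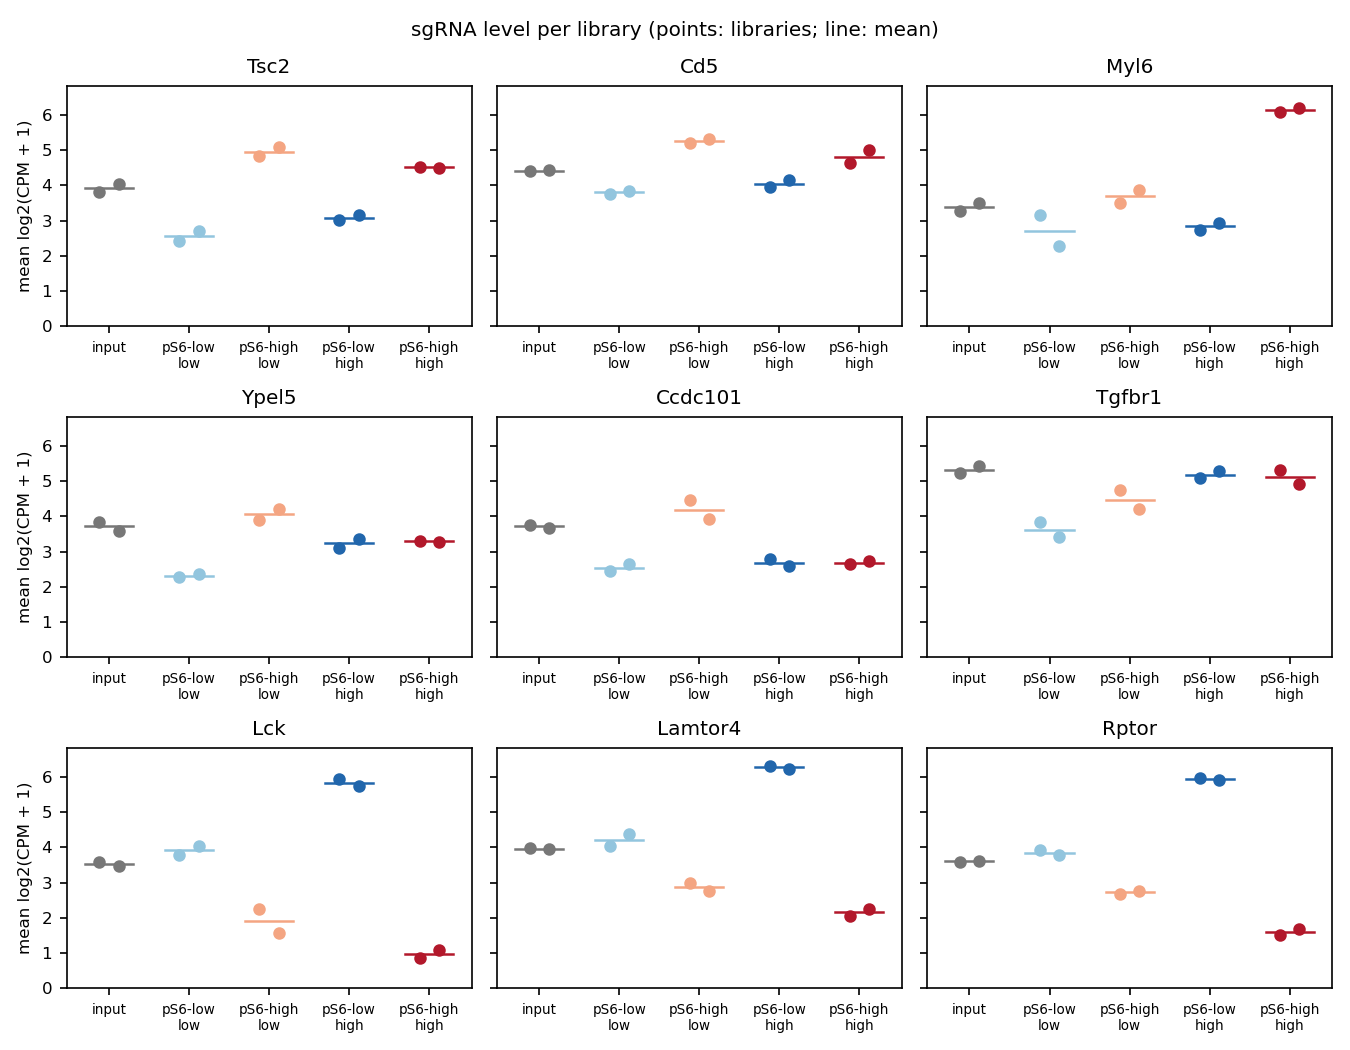
Mean log2(CPM + 1) over the sgRNAs of 9 genes in each group; points are the 2 libraries and lines their mean. Lamtor4 stood at 3.97 in the input, 4.20 in pS6-low cells at the low dose and 6.27 in pS6-low cells at the high dose, and Ypel5 at 4.06 and 2.32 in pS6-high and pS6-low cells at the low dose against 3.29 and 3.24 at the high dose.

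Comparison of all sorted cells with the input asked which knockouts differed between the mean of the sorted groups and the input. The sorted groups had equal weight on the log scale, and shares of cells per gate were not analysed here. A knockout's shift between gates can therefore move this mean without a gain or loss of its cells. Bcl2, which protects T cells from apoptosis, was lower in sorted cells by −1.47 ± 0.13 (log2, mean over 4 sgRNAs, 8 sorted against 2 input libraries). Ncbp1, which binds the cap of mRNA, changed by −1.59 ± 0.21, Med12, a Mediator subunit gene, by −1.53 ± 0.12, and Tgfbr1 by −0.77 ± 0.14. Atp2a2 (0.72 ± 0.09), Nrbp1 (0.58 ± 0.03), Atp2b1 (0.48 ± 0.04), Coro1a (0.47 ± 0.06) and Myl6 (0.46 ± 0.13) were higher in sorted cells. Foxp3, the lineage factor of regulatory T cells, was called as lower (−0.85 ± 1.29, adjusted p = 3.65e-06), but 1 of its 4 sgRNAs rose and 3 fell. That sgRNA rose 9.47-fold, from a mean of 25 CPM in the input to 237 CPM in sorted cells, while the others fell 2.26-fold, 5.40-fold and 5.77-fold. With counts summed per gene the direction of Foxp3 turned to 1.27 (adjusted p = 6.32e-07).

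**Figure D4:**
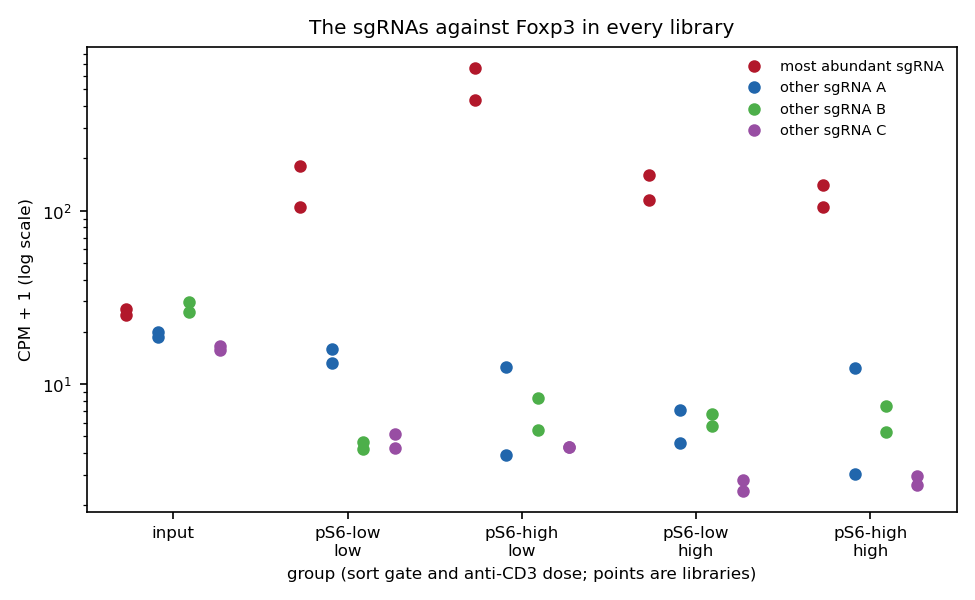
CPM + 1 (log axis) of the 4 Foxp3 sgRNAs by group; points are libraries and colours sgRNAs. The sgRNA that rose had means of 547 CPM in pS6-high and 142 CPM in pS6-low cells at the low dose, against 25 CPM in the input.

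Sorted cells had 16 genes called as higher and 205 as lower than the input among 19640 tested by edgeR, with adjusted p of 8.22e-10 for Atp2a2 and 4.89e-09 for Bcl2, and 1420 genes had an unadjusted p below 0.05. The cytosolic ribosomal protein genes made up 32 of the 205 (of 80 tested, median −1.18), SAGA 6, V-ATPase 4, TGF-beta and Treg identity 3 and the proteasome and the positive TCR regulators 1 each. These counts depended on the processing and on single libraries. The 205 became 17 at equal depth, where 14 of the 80 ribosomal protein genes could still be tested, 90 with the filter of 50 counts, 81 with counts summed per gene, 23 without each gene's strongest sgRNA, 41 without input replicate 1, 126 without input replicate 2 and 120 without pS6-high replicate 2 of the high dose. The 16 became 1 at equal depth, where Atp2a2 kept its call and Nrbp1 (adjusted p = 0.154), Atp2b1 (0.12), Coro1a (0.270) and Myl6 (0.234) lost theirs. They became 5 with counts summed per gene, which ended the calls of Coro1a (0.0641) and Myl6 (0.116), 5 without each gene's strongest sgRNA, 4 without input replicate 1, 10 without pS6-high replicate 2 and 9 without pS6-low replicate 2 of the low dose. The calls of Ccdc101 (−0.76 ± 0.15; adjusted p = 0.0536), Myl6 (0.240) and Coro1a (0.0940) were lost without input replicate 1, and that of Coro1a also without input replicate 2 (0.0678).

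In the input itself, sgRNAs of some lists were scarcer than others. The median log2(CPM + 1) was 3.72 over all sgRNAs, and the median of cytosolic ribosomal protein sgRNAs lay below it by a log2 difference of −1.98, that of the proteasome by −1.23, V-ATPase by −0.82 and IL-2, JAK and STAT by −0.80 (mean of 2 libraries, not tested). The ribosomal difference was −0.69 with the filter of 50 counts, which removes scarce sgRNAs. Mitochondrial ribosomal proteins (0.01), complex I (−0.02) and olfactory receptors (0.07) lay close to all sgRNAs. A plasmid library was not used here, so these differences also contain the composition of the library before transduction. Low starting levels reduce the counts behind sort effects of the scarce lists.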

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

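The tests for a common stretch, for clonal outgrowth of Foxp3 knockouts and for equal depth of ribosomal sgRNAs were chosen only after the results were seen. The sort effects that differed between doses by a test of the difference itself numbered 3 towards pS6-high and 55 towards pS6-low at the high dose. Among the named genes, the differences of log2 fold changes were −4.48 for Actr2, −5.23 for Mtor, −3.64 for Rptor, −2.99 for Rraga, −2.88 for Lamtor4, −2.77 for Lamtor3, −2.53 for Cd3e, −2.26 for Wdr24, −2.24 for Zap70 and −2.01 for Rheb. They were −1.70 for both Smarcb1 and Ccdc101, −1.07 for Tsc2, 0.80 for Atp2a2, 1.13 for Ptbp1 and 2.32 for Myl6. Of the 35 splits of the 8 sorted libraries into 4 and 4, 1, the real one, gave as many as 520 called genes over both doses. The highest of the others gave 230, the split by dose 116 and the split by replicate number 0.

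Knockouts enriched in pS6-low cells, Lamtor4 and Mtor among them, had larger fold changes at the high dose, where the pS6-high libraries were shallower and the pS6-low libraries deeper than at the low dose. With all libraries thinned to equal depth, the median difference over 358 genes called towards pS6-low in both doses together was −0.54. The 95% interval over genes was −0.62 to −0.44, and the value without thinning was −0.56. Thinning leaves CPM the same on average, so this median could hardly move. It cannot decide how far unequal depth contributed. A common stretch of every sort effect would also enlarge effects towards pS6-high. The ratio of mean high-dose to mean low-dose log2 fold change was 0.979 (0.871 to 1.10) over 157 genes called towards pS6-high, against 1.73 (1.63 to 1.83) over 363 genes called towards pS6-low. For positive TCR regulators, median log2(CPM + 1) in pS6-low libraries was 3.73 and 3.75 at the low and 4.46 and 4.36 at the high dose. In pS6-high libraries it was 2.90 and 2.60, then 2.74 and 2.65. The Rag GTPase list rose from 3.82 and 3.98 to 4.71 and 4.59 in pS6-low libraries. In pS6-high libraries that list fell from 3.36 and 3.45 to 3.02 and 3.17. Stronger stimulation may make pS6 depend more on genes whose knockouts were enriched in pS6-low cells. Alternatively, the pS6-low gate may have held a smaller share of cells at the high dose, which could concentrate such knockouts there. Both stay open, since shares of cells per gate were not analysed here.

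Ribosomal protein sgRNAs were lower in sorted cells than in the input, with a median log2 ratio of arithmetic mean CPM of −0.71 (95% interval over 308 sgRNAs −0.75 to −0.63) against 0.01 over all sgRNAs, which argues against an effect of averaging logs. Olfactory receptor sgRNAs matched on CPM in input replicate 1 had a median log2 ratio of sorted cells to input replicate 2 of −0.10 against −0.52 for ribosomal sgRNAs. The difference of 0.42 (0.30 to 0.55) argues against low counts as the whole cause. At equal depth, where 14 of the 80 genes kept enough sgRNAs for the gene test, the ratio over all 308 sgRNAs was −0.67 (−0.78 to −0.52). Thinning leaves a mean CPM the same on average, so this ratio could hardly move. It cannot decide how far unequal depth contributed to the gene calls. Loss of cells that need ribosomal proteins between the input and the sort is consistent with these values but was not tested, and a difference in handling between input and sorted libraries stays open.

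Of the Foxp3 sgRNAs, 1 rose and 3 fell from the input to sorted cells, and the former supplied the most abundant sgRNA of 7 of the 8 sorted libraries. Chance outgrowth of a few clones in a single culture could raise 1 sgRNA alone. The CPM of this sgRNA differed between replicates of a sorted group by at most 1.72-fold, with 547 ± 164 CPM in pS6-high and 142 ± 53.2 CPM in pS6-low cells at the low dose (mean ± SD, 2 libraries each). That argues against outgrowth in single libraries, but outgrowth before the replicates were divided stays open, as the labels do not say whether they are separate cultures. No biological explanation was tested.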

How the results depend on the processing

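Equal depth was the only alternative added after the data were seen. Of the named genes' 245 calls, 173 held under every alternative other than leaving out a library and 167 under every left-out library, and of 48 list calls 37 held in each case. No call of a named gene was lost with DESeq2's size factors, with at least 50 counts or with at least 2 sgRNAs per gene; 8 were lost with DESeq2's test per sgRNA, 26 at equal depth and 64 without each gene's strongest sgRNA. Counts summed per gene gave 191 genes towards pS6-high and 325 towards pS6-low at the low dose, 271 and 604 at the high dose, 258 and 559 over both, 20 and 115 for the difference between doses, and 5 higher and 81 lower in sorted cells than in the input; the cause was not tested. Under this setting Foxp3 reversed to 1.27 in sorted cells against input, because its most abundant sgRNA then carries the sum. Without each gene's strongest sgRNA, which leaves fewer sgRNAs per gene, the counts were 43 and 72 at the low dose, 43 and 146 at the high dose, 72 and 189 over both, 1 and 20 for the difference, and 5 and 23 against the input. Equal depth, which removes counts, gave 1 and 17 genes against the input, and the filter of 50 counts, which removes scarce sgRNAs, gave 90 lower genes there. Ribosomal protein sgRNAs lay below all sgRNAs in the input by a log2 difference of −2.33 with log2(CPM + 0.1) and −0.69 with that filter. Across left-out libraries, the ranges were 47 to 76 and 69 to 166 genes at the low dose, 56 to 69 and 164 to 238 at the high dose, 121 to 155 and 276 to 356 over both, 2 to 5 and 32 to 49 for the difference, and 4 to 16 and 41 to 219 against the input. Camera's lists past the threshold ranged from 12 to 17, 13 to 15 and 15 to 17. Libraries of equal replicate number deviated from their group means with correlations across sgRNAs of 0.0203 to 0.0658. These were small but all above 0, so a shared culture is not excluded. As the labels do not settle it, the numbers were not taken to pair libraries. A replicate block gave 104 and 175 genes at the low dose, 85 and 279 at the high dose, 156 and 354 over both, 4 and 57 for the difference and 18 and 189 against the input, and ended no list call; of named genes it ended the call of Tada1 over both doses (adjusted p = 0.0510) and added those of Atp2b1 and Mios for the difference. The shallow pS6-high libraries of the high dose, with medians of 30 and 56 counts per sgRNA, limit folds of strongly depleted knockouts. Scaling on non-targeting sgRNAs and a null distribution from them were not run.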

Other observations

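All groups of this part were assembled, and their tests chosen, only after the gene tables were seen, so their p-values overstate the evidence. Of 12 genes of the CTLH ubiquitin ligase, 5 were called towards pS6-high at the low dose: besides Ypel5 and Ube2h, Maea (1.54 ± 0.39), Wdr26 (1.24 ± 0.07) and Gid8 (0.95 ± 0.22) were called there, while Rmnd5a (0.07 ± 0.18) and Armc8 (−0.16 ± 0.05) were not. At the high dose 0 were called (Maea −0.35 ± 0.34), and the difference between doses was called for 4 and not for Gid8 (−0.69 ± 0.32). Camera, adjusted over the 13 groups assembled, gave 2.23e-14 at the low dose (0.00414 with an estimated correlation), 0.213 at the high dose and 1.37e-11 for the difference (0.0146 with an estimated correlation). The Sec61 translocon and signal sequence receptor had 5 of 11 genes called towards pS6-high at the low dose, with Sec61a1 at 1.01 ± 0.25, and 1 at the high dose, with adjusted p = 2.64e-14 and 0.252 (0.000827 and 0.256 with an estimated correlation). The actin regulators Arp2/3, WASP and WAVE went to pS6-low with 8 of 17 genes called at the low and 10 at the high dose, Arpc2 at −1.46 ± 0.31 and −4.94 ± 0.55 and Wipf1 at −1.56 ± 0.20 and −2.52 ± 0.50. Their difference between doses had adjusted p = 2.55e-30 (0.00255 with an estimated correlation). Integrin activation had 7 and 6 of 14 genes called towards pS6-low, with Tln1 at −1.61 ± 0.35 and −2.73 ± 0.33 and Itgb3 at −1.46 ± 0.15 and −1.92 ± 0.16. Of 20 cytosolic aminoacyl-tRNA synthetases, 2 were called towards pS6-low at the low dose and 16 at the high dose, Sars at −1.08 ± 0.27 and −2.94 ± 0.35.

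Over both doses together, a group of cell-cycle regulators from RB and the DREAM complex had 7 of 12 genes called towards pS6-high. Among them were Rbbp4 (1.59 ± 0.24), Lin9 (1.39 ± 0.35) and Rb1 (1.07 ± 0.24). Camera gave adjusted p = 1.60e-25 (0.00101 with an estimated correlation). The other members were not called: Rbl1 (−0.30 ± 0.08), Rbl2 (−0.12 ± 0.12), E2f4 (−0.03 ± 0.15), E2f5 (0.21 ± 0.12) and Tfdp2 (0.25 ± 0.20). The group therefore did not move as a whole. Neddylation and cullins had 11 of 17 called towards pS6-high, such as Tceb1 (now Eloc, 1.38 ± 0.27) and Arih1 (1.12 ± 0.20), and Cul1 towards pS6-low (−1.34 ± 0.11). The cobalamin and folate cycle had 6 of 13 called towards pS6-high, such as Mtr (1.03 ± 0.17). Nonsense-mediated decay (5 of 10, Smg1 1.28 ± 0.20) and the conjugation of ATG8 and ATG12 (4 of 7, Atg5 0.59 ± 0.09) went to pS6-high, and TFIID to pS6-low (8 of 12, Taf2 −2.46 ± 0.26). Calcium pumps and calcineurin (2 towards pS6-high and 3 towards pS6-low of 13, adjusted p = 0.257) and the COMPASS histone methyltransferases (2 and 2 of 11, 0.795) moved in no common direction.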
